A study of Homo sapiens with 36 samples.

How the data were processed

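RNA was measured in 36 libraries from 2 human leukemia cell lines. K562 is a line with erythroid features derived from chronic myeloid leukemia in blast crisis, and HEL is an erythroleukemia line. The series concerns LMO2, an adaptor protein with no DNA binding of its own, LDB1, which bridges complexes held by LMO2, and TAL1, a DNA-binding partner of LMO2 in blood cells. The first set holds 24 libraries from K562: a parental line, a line the labels call LMO2 control, and LMO2 degron cells labelled rep 1 and rep 2, read here as 2 degron lines. Each was sampled on day 0 without dTAGv1 and on days 1 and 4 with dTAGv1 (750 uM as the labels give it, a unit that may be a typing error for nM), with 2 libraries per line and day labelled bio rep 1 and 2. A degron is a tag through which dTAGv1, a molecule that binds the tag and an E3 ubiquitin ligase, marks the tagged protein for breakdown. What the LMO2 control line carries is not given in the sources used here. The second set holds 9 HEL libraries, 3 with a non-targeting siRNA pool and 3 with each of 2 TAL1 siRNA pools. The third holds 3 K562 libraries, 1 with a control shRNA and 1 with each of 2 LDB1 shRNAs.

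For the K562 degron set the authors deposited FPKM, fragments scaled to gene length and library size, for 60642 genes. For HEL the authors deposited raw counts per gene for 57820 genes, 2055 of whose symbols stand on more than 1 line. For the LDB1 set the authors deposited TPM, transcripts scaled to length and to a common total, for 13707 genes. Their sums (972556 to 976400) fall short of that total, and the rule that chose these genes is not given in the sources used here. Per the submitters' processing notes, FastQC, STAR and featureCounts and the build hg19 were used, and neither versions, annotation nor strand setting are given in the sources used here. The symbol styles of the FPKM and count tables differ, and which annotation each used is unknown. Per the labels' protocols, K562 and HEL libraries were prepared by different providers, and every test stayed within 1 table. Reads from genes with near-identical copies (HBA1 and HBA2, HBG1 and HBG2, histone and ribosomal protein genes) could have been split between copies, and reads of overlapping antisense genes cannot be told apart without strand, so values of such genes are uncertain.

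FPKM values were analysed as log2(FPKM + 1), with a pseudocount of 1 that understates changes of low genes. The 15348 genes with at least 1 FPKM in at least 2 libraries were fitted in 1 linear model with 12 line-by-day groups in limma 3.58.1 (R 4.3.3; empirical Bayes with trend and robust settings). The degron-specific change was the mean change from day 0 over the 2 degron lines minus that over the parental and LMO2 control lines, together called the control lines. HEL counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, robust fit, genes passing filterByExpr, 16688 in all) in 1 fit of the 9 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p for single genes comes from limma for the degron set and edgeR for HEL. LDB1 libraries had 1 library per group and so no test: a gene was counted at a log2 ratio of (TPM + 1) of at least 1 in size and of equal sign in both shRNA libraries, with a highest TPM of at least 5 (12445 of the listed genes reach that). Errors beside log2 changes are standard errors, and those beside FPKM or CPM are SD.

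In all, 27 gene lists were tested where at least 5 members passed the filter: LMO2 complex and partners, globins, heme synthesis and mitochondrial iron import, erythroid membrane and surface, erythroid transcription factors, megakaryocyte and platelet, monocyte and granulocyte, mast cell and basophil, stem and progenitor, lymphoid, fibroblast and stroma, S phase, G2 and M phase, MYC and ribosome biogenesis, cholesterol synthesis, integrated stress and unfolded protein response, interferon response, p53 targets, apoptosis regulators, HIF targets, iron handling, JAK-STAT feedback, immediate early, autophagy and lysosome, mitochondrially encoded, replication-dependent histones, and ribosomal proteins. The test was camera in limma with a preset correlation of 0.01, repeated with an estimated correlation and with fry, and adjusted over the lists of a comparison. For LDB1 libraries a list's median was placed among 10000 random lists of equal size matched on mean expression. Older symbols were matched through RefSeq synonyms that belong to 1 gene, PECAM1 stayed unmatched in the counts and HIST1H2BC in the FPKM table, and the TPM table lacks more members.

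Genes named in the text followed a rule: LMO2, LDB1 and TAL1 always, the 8 largest rises and 8 largest falls among called genes with mean level of at least 5 FPKM or CPM (highest TPM of at least 10 for LDB1) moving one way in both degron lines, pools or shRNAs, and up to 4 members per list, called ones by smallest adjusted p (LDB1: by ratio), otherwise the highest expressed member. Symbols such as LOC, LINC, MIR and SNOR names, or AC and AL with digits, were left out of the rule, and some genes that met the rule are not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Chosen after seeing the data were the comparison of day 4 with day 1, HEL without its replicate 1 libraries, thinned counts, equal-sized lists from simulated groups, splits by HEL replicate number, LDB1 lists in the degron set and genes moving in all 3 systems. Alternatives were another pseudocount, other filters, trimmed-mean rescaling, DESeq2 1.42.0, RLE factors, limma voom, other sets of control or degron lines, a replicate block, other TPM rules, and each library left out in turn. Where that leaves a line and day with 1 library, the fit pools the spread, so the lone library is taken to vary like the other groups. Depths and figures were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

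Low FPKM values lay on whole multiples of 1 read: over 20342 single-exon genes, 95.1% to 96.0% of values of up to 10 reads lay within 2% of a whole number, which gives 17.2 M to 26.3 M reads per library. Replicate numbers of the degron set were checked for pairing: between the 12 groups, deviations of same-numbered libraries from their group means correlated in all 66 pairs (r 0.119 to 0.662, median 0.377, across genes, which are not independent replicates). These numbers were therefore taken to pair the libraries by the data, while the labels give only a bio rep number. No library was a duplicate by sampling noise: HEL pairs differed with chi-square per degree of freedom of 4.39 to 30.6, and replicate pairs in the FPKM table shared 0% of values (r 0.948 to 0.982). The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The methods were tested on simulated data with 100 genes changed per fold. For the day 4 contrast (15348 genes), 19% of 1.5-fold and 58% of 2-fold changes were recovered with 3 false calls (3.75% of calls), and for HEL with both pools (16688 genes) 41% and 54%, with 7 false calls (6.86%). No column of per-sample values was left unused. The genome of the build was not used here, so no coordinates are given.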

Results

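The series was designed to ask which transcripts depend on the LMO2, LDB1 and TAL1 complex in leukemia cells. RNA was sequenced from 24 K562 libraries of the LMO2 degron set (4 lines, 3 days, 2 libraries each), 9 HEL libraries of TAL1 knockdown (3 groups of 3) and 3 K562 libraries of LDB1 knockdown (1 per group). HEL libraries held 15.9 M to 27 M counts, K562 degron libraries 17.2 M to 26.3 M reads as recovered from their FPKM, and the depth of the LDB1 libraries is unknown.

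As a first step, LMO2 RNA was examined in each degron-set group. A degron acts on the protein, so this RNA does not test protein loss. On days 0, 1 and 4, LMO2 stood at 34.7 ± 3.5, 38.9 ± 10.9 and 41 ± 4.50 FPKM (n = 2) in parental cells and at 249.9 ± 2.74, 270.0 ± 81.8 and 365 ± 111 in the LMO2 control line. It stood at 139 ± 10.1, 186 ± 81.9 and 213 ± 82.3 in degron line 1 and at 146 ± 15.9, 188 ± 58.5 and 249.6 ± 21.8 in degron line 2. The degron-specific change of LMO2 was 0.23 ± 0.34 (adjusted p = 0.989) on day 1 and 0.29 ± 0.34 (adjusted p = 0.595) on day 4, both within the spread. TAL1 did not pass either test (-0.41 ± 0.40 (adjusted p = 0.967) and -0.33 ± 0.40 (adjusted p = 0.614)). LDB1 RNA went from 82.3 ± 11.7 to 52.2 ± 0.397 and 43.5 ± 3.80 FPKM in degron line 1 and from 71.7 ± 2.15 to 36.7 ± 1.02 and 35.5 ± 5.08 in line 2. Its degron-specific change was -0.75 ± 0.17 (adjusted p = 0.130) on day 1, called with the replicate number as a block (adjusted p = 0.00651), and LDB1 fell on day 4 (-0.89 ± 0.17 (adjusted p = 0.002)).

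The earliest response was then measured as the degron-specific change after 1 day of dTAGv1. KLF1, an erythroid transcription factor, fell most among the genes called on day 1 (-1.82 ± 0.20 (adjusted p = 0.00403)). Its FPKM went from 121 ± 17.2 to 47.2 ± 1.83 in degron line 1 and from 83.5 ± 17.3 to 15.4 ± 1.04 in line 2 (n = 2). In parental cells it was 111 ± 21.9 and 107 ± 32.6. MYC, a transcription factor of cell growth (-1.32 ± 0.22 (adjusted p = 0.0399)), and NFE2, an erythroid and megakaryocytic transcription factor (-1.21 ± 0.18 (adjusted p = 0.0256)), also fell. So did CDC42EP1, an effector of the GTPase CDC42 (-1.12 ± 0.14 (adjusted p = 0.00991)). MYC already stood lower in the degron lines on day 0 (-1.02 ± 0.16 (adjusted p = 0.000349)). UROD, an enzyme of heme synthesis (-0.76 ± 0.12 (adjusted p = 0.0276)), TTLL12 (-0.72 ± 0.10 (adjusted p = 0.0256)), DHRS11 (-0.75 ± 0.12 (adjusted p = 0.0324)) and C2orf88 (-0.75 ± 0.13 (adjusted p = 0.0493)) fell by smaller amounts. PLCB2, a phospholipase of G-protein signalling (0.90 ± 0.16 (adjusted p = 0.0493)), and CYTH1, an exchange factor for ARF GTPases (0.67 ± 0.10 (adjusted p = 0.0276)), rose. In all, 12 of 15348 genes were called (4 higher, 8 lower, 1069 at unadjusted p under 0.05). The other 2 called genes, named after their values were seen, were ITGAX, an integrin of myeloid cells (0.82 ± 0.12 (adjusted p = 0.0256)), and AC092115.4 (1.07 ± 0.17 (adjusted p = 0.0293)). All 12 had 1 sign in both bio reps and in both degron lines, which calling them on these same libraries favours.

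With the replicate number as a block, 167 genes were called on day 1 (71 higher, 96 lower). Leaving out 1 library gave 1 to 12 calls. A total of 1 remained without LMO2 control day 0 replicate 2, degron line 1 day 1 replicate 1 or degron line 2 day 1 replicate 1. Omitting LMO2 control day 0 replicate 1, degron line 1 day 0 replicate 2, degron line 2 day 0 replicate 1 or LMO2 control day 1 replicate 2 left 2. A total of 3 remained without parental day 0 replicate 2 or degron line 1 day 0 replicate 1. Omitting LMO2 control day 1 replicate 1 left 5. A total of 6 remained without parental day 0 replicate 1, degron line 2 day 0 replicate 2, parental day 1 replicate 1 or degron line 2 day 1 replicate 2. KLF1 stayed called in all 16 such fits, but not with lines as replicates (adjusted p = 0.0643), parental cells as the only control (0.0627) or degron line 1 alone (0.370). CDC42EP1 was lost in 3 of the 16, without LMO2 control day 0 replicate 2 or day 1 replicate 1 of either degron line. Among these fits MYC stayed called only without parental day 1 replicate 1, LMO2 control day 1 replicate 1, degron line 1 day 1 replicate 2 or degron line 2 day 1 replicate 2. NFE2 stayed called only without parental day 0 replicate 1, parental day 1 replicate 2, degron line 1 day 1 replicate 2 or degron line 2 day 1 replicate 2. UROD did so only without degron line 2 day 0 replicate 2, parental day 1 replicate 2 or degron line 1 day 1 replicate 2. CYTH1 stayed called only without parental day 1 replicate 1, parental day 1 replicate 2 or degron line 1 day 1 replicate 2. PLCB2 did so only without degron line 2 day 0 replicate 2 or parental day 1 replicate 2, while C2orf88 did so only without LMO2 control day 1 replicate 1 and DHRS11 only without degron line 2 day 0 replicate 2. TTLL12 lost its call in 8 fits. None of these 16 fits used the block, so differences between bio reps stayed in their spread. A call lost or missing without the block may reflect that spread.

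Gene lists showed in which direction groups of genes moved on day 1. Of 12 erythroid transcription factors, KLF1 and NFE2 fell (4 fell with the block, 5 adjusted over the list alone). The list as a whole gave camera adjusted p = 1.87e-08, or 0.0193 with an estimated correlation, 0.115 with the block as well. Of 10 globins, none passed (1 with the block), the median was -0.74 and HBZ, an embryonic globin, stood at -0.84 ± 0.73 (adjusted p = 0.958). Tested as a group, the list gave camera adjusted p = 0.00572, or 0.456 with an estimated correlation. UROD was the only called gene of 14 in heme synthesis, with 2 lower and 1 higher adjusted over the list alone. Here camera gave adjusted p = 0.00572, or 0.481 with an estimated correlation. None of 23 erythroid membrane genes passed (3 with the block, 2 adjusted over the list alone), with a median of -0.47 and RHAG, a membrane channel of red cells, at -0.40 ± 0.20. The members together gave camera adjusted p = 3.75e-08, or 0.315 with an estimated correlation. Among 24 genes of MYC and ribosome biogenesis MYC alone fell (3 with the block, 1 adjusted over the list alone). Over all members the test gave camera adjusted p = 3.11e-09, or 0.315 with an estimated correlation. No member passed of 25 S phase genes (median -0.30, PCNA -0.35 ± 0.28). Camera gave adjusted p = 3.75e-08, or 0.315 with an estimated correlation. None of 24 cholesterol synthesis genes did either (1 with the block, 1 adjusted over the list alone; INSIG1 -0.44 ± 0.20). The list rose in control lines (below), which lowers its degron-specific change. Camera gave adjusted p = 0.00130, or 0.315 with an estimated correlation. Of 14 genes of the LMO2 complex none passed (2 with the block, 4 lower and 1 higher adjusted over the list alone). These genes gave camera adjusted p = 0.0261, or 0.315 with an estimated correlation. HIF targets had 0 of 19 passing (1 with the block; camera adjusted p = 0.0261, or 0.651 with an estimated correlation). Monocyte and granulocyte genes lay higher, with 0 of 11 passing and 3 adjusted over the list alone (median 0.29). The list as a whole gave camera adjusted p = 0.00130, or 0.180 with an estimated correlation. Interferon genes lay higher too, with 0 of 11 passing (camera adjusted p = 0.01, or 0.315 with an estimated correlation).

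Lists without a camera call on day 1 were stem and progenitor (adjusted p = 0.0971), G2 and M phase (0.238), integrated stress (0.379), p53 targets (0.305), apoptosis regulators (0.215), iron handling (0.140), autophagy and lysosome (0.348), mitochondrially encoded (0.433) and ribosomal proteins (0.0974). Median, mean and test differed in sign for megakaryocyte genes (median 0.12, mean -0.12, test lower, adjusted p = 0.706) and JAK-STAT feedback (median 0.23, mean 0.01, test lower, 0.456). They also differed for immediate early genes (median -0.00, mean 0.02, test higher, 0.706) and histones (median 0.04, mean 0.06, test lower, 0.718). Mast cell, lymphoid and stromal lists had 3, 4 and 4 tested members in this table and no list test, and none of these members was called on day 1.

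**Figure D1:**
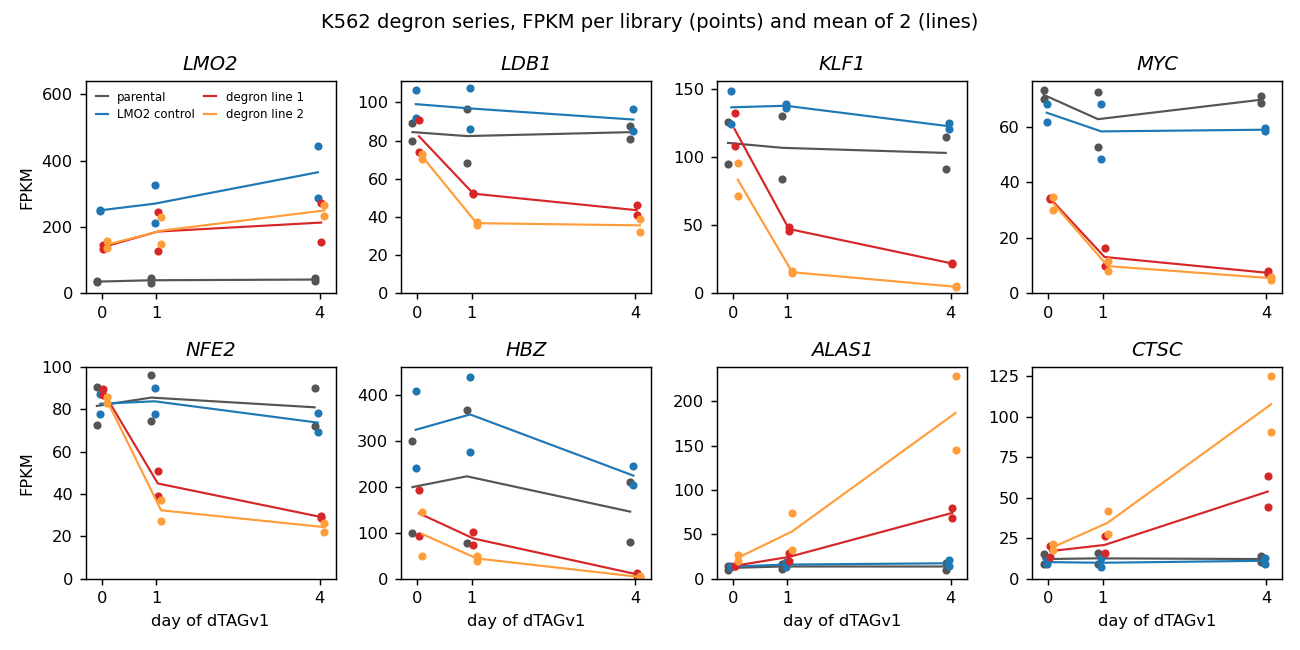
FPKM of 8 genes against day of dTAGv1 in the parental, LMO2 control and 2 degron lines, with 1 point per library and lines through the mean of 2. KLF1, MYC and NFE2 go down from day 0 in both degron lines by day 1 and HBZ by day 4, while ALAS1 and CTSC go up by day 4. MYC already lies lower in the degron lines on day 0.

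After 4 days of dTAGv1 the degron-specific change took in many more genes. KLF1 fell further (-3.02 ± 0.20 (adjusted p = 7.56e-07)), to 21.8 ± 0.990 FPKM in degron line 1 and 4.71 ± 0.574 in line 2, with 103 ± 16.9 in parental cells (n = 2). HBZ and HBM, 2 globins, HEMGN, a nuclear protein of blood cell precursors, PKLR, pyruvate kinase of liver and red cells, EGFL7, a secreted vascular factor, and FAM178B were among the largest falls. Their changes were HBZ (-3.52 ± 0.73), HBM (-3.32 ± 0.80), FAM178B (-3.26 ± 0.65), EGFL7 (-3.24 ± 0.51), HEMGN (-3.21 ± 0.79) and PKLR (-2.86 ± 0.69), with adjusted p = 0.000585 to 0.0102. The transcript AP001531.1 fell by 4.31 ± 0.46 (adjusted p = 2.77e-05). ALAS1, the enzyme that opens heme synthesis in non-erythroid cells, rose by 2.36 ± 0.38 (adjusted p = 0.000634). It went from 14.6 ± 0.0595 to 74.2 ± 7.76 FPKM in line 1 and from 23.6 ± 5.16 to 187 ± 58.3 in line 2. Parental cells had 12.2 ± 3.69 and 13.8 ± 6.10. Further rises were seen for SYT10, a vesicle calcium sensor, SOSTDC1, a secreted BMP antagonist, P2RX6, an ATP-gated channel subunit, CCL24, a chemokine, CTSC, a lysosomal protease, and SCPEP1, a carboxypeptidase. These were SYT10 (2.28 ± 0.28), SOSTDC1 (2.13 ± 0.38), P2RX6 (2.03 ± 0.22), CCL24 (1.97 ± 0.33), CTSC (1.93 ± 0.36) and SCPEP1 (1.90 ± 0.21), with adjusted p = 3.26e-05 to 0.00192. ARRDC4 also rose (1.94 ± 0.54 (adjusted p = 0.0208)), a call lost without replicate 1 of either degron line on day 0 or day 4. In all, 3040 of 15348 genes were called, 1784 higher and 1256 lower, of which 344 and 386 changed at least 2-fold. The balance depended on low genes and scaling: it was 783 higher and 991 lower at a mean FPKM of at least 5, 1416 and 1297 with a pseudocount of 0.1, and 1509 and 1330 after trimmed-mean rescaling. Every called gene had 1 sign in both bio reps, and 3039 of 3040 in both degron lines.

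With the replicate number as a block 5471 genes were called (3080 higher, 2391 lower), and leaving out 1 library gave 2362 to 3312. Fewer were called with degron line 1 alone (1398), and more against the control lines of day 4 without day 0 (8315).

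The erythroid lists were examined first on day 4. Of 10 globins, 5 fell and 1 rose (8 and 1 with the block, 6 and 1 adjusted over the list alone). Tested as a group, the list gave camera adjusted p = 0.00328, or 0.380 with an estimated correlation. HBQ1, the theta globin (-2.23 ± 0.38 (adjusted p = 0.000963)), HBZ and HBM fell and HBD, the delta globin, rose (1.72 ± 0.30 (adjusted p = 0.00105)). HBA1 (-2.40 ± 0.71 (adjusted p = 0.0269)) and HBA2 (-2.39 ± 0.80 (adjusted p = 0.0488)), named after their values were seen, also fell, and their calls were not tested with libraries left out. Of 23 erythroid membrane genes, 5 fell and 1 rose (11 and 1 with the block, 10 and 1 adjusted over the list alone). For this list, the group test gave camera adjusted p = 0.00149, or 0.473 with an estimated correlation. SPTB, erythroid beta spectrin, RHD, a blood group antigen, TFRC, the transferrin receptor, and GYPC, a glycophorin, fell: SPTB (-1.90 ± 0.27), RHD (-2.47 ± 0.54), TFRC (-0.97 ± 0.23) and GYPC (-1.48 ± 0.39). Of 12 erythroid transcription factors, 6 fell (7 fell and 2 rose with the block, 6 fell and 1 rose adjusted over the list alone). The members together gave camera adjusted p = 0.000983, or 0.0963 with an estimated correlation. NFE2, GFI1B, a repressor, and GATA1, a partner of the LMO2 complex, fell by this test: NFE2 (-1.57 ± 0.18), GFI1B (-1.15 ± 0.18) and GATA1 (-0.86 ± 0.13), adjusted p = 5.36e-05 to 0.000610. Genes of heme synthesis went both ways, 2 of 14 higher and 2 lower (2 and 4 with the block, 2 and 2 adjusted over the list alone; camera adjusted p = 0.135). UROD fell and ALAD and TMEM14C rose (UROD (-1.24 ± 0.12), ALAD (1.03 ± 0.14) and TMEM14C (0.72 ± 0.16)). Of 14 genes of the LMO2 complex, 5 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.150). GATA1 and TCF3, an E protein, were lower (-0.67 ± 0.13 for TCF3) and SSBP2, a partner of LDB1, higher (0.84 ± 0.15).

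Lists of growth and metabolism were lower. S phase genes fell in 17 of 25 cases (20 adjusted over the list alone). Over all members the test gave camera adjusted p = 1.03e-14, or 0.117 with an estimated correlation. Examples were the helicase subunits MCM7 and MCM2, TYMS and RRM1: MCM7 (-1.44 ± 0.16), MCM2 (-1.12 ± 0.15), TYMS (-1.07 ± 0.15) and RRM1 (-0.88 ± 0.14). G2 and M phase genes fell in 19 of 24 (19 adjusted over the list alone). The group test here gave camera adjusted p = 4.64e-15, or 0.0535 with an estimated correlation. Spindle and kinetochore genes among them were AURKA, TPX2, CENPA and BUB1B: AURKA (-1.01 ± 0.11), TPX2 (-1.03 ± 0.12), CENPA (-1.18 ± 0.14) and BUB1B (-1.08 ± 0.15). Of 24 cholesterol synthesis genes 15 fell (15 adjusted over the list alone; camera adjusted p = 3.51e-12, or 0.0535 with an estimated correlation). INSIG1, a regulator of sterol synthesis, MVD and DHCR7 were among them: INSIG1 (-2.57 ± 0.20), MVD (-1.46 ± 0.16) and DHCR7 (-1.33 ± 0.16). Of 24 genes of MYC and ribosome biogenesis 6 fell (19 with the block, 7 adjusted over the list alone). Taking all members at once gave camera adjusted p = 5.41e-07, or 0.368 with an estimated correlation. Among them were MYC, FBL, a nucleolar methyltransferase, NOB1 and LDHA: MYC (-2.14 ± 0.22), FBL (-1.35 ± 0.15), NOB1 (-0.74 ± 0.13) and LDHA (-1.73 ± 0.35). Ribosomal protein genes fell in 13 of 27 (27 with the block, 18 adjusted over the list alone), such as RPS6 (-0.78 ± 0.13) and RPS19 (-0.93 ± 0.17). As a group these genes gave camera adjusted p = 1.14e-10, or 0.344 with an estimated correlation. HIF targets had 6 lower and 1 higher of 19 (12 and 1 with the block, 7 and 1 adjusted over the list alone). The list as a whole gave camera adjusted p = 0.000450, or 0.380 with an estimated correlation. HK2 and CA9 were lower and CA12 higher: HK2 (-2.04 ± 0.48), CA9 (-2.12 ± 0.50) and CA12 (1.05 ± 0.26). Histone genes fell in 3 of 12 (4 adjusted over the list alone), for example H1-2 (-1.58 ± 0.34). Tested as a group, the list gave camera adjusted p = 0.000404, or 0.136 with an estimated correlation.

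A smaller number of lists lay higher on day 4. CSF3R, IFIT2, BCL2A1 and COL3A1 reached 1 FPKM only in degron cells on day 4 (at most 0.716, 0.730, 0.454 and 0.302 FPKM elsewhere). They passed the filter only by rising, which favours rises in the monocyte, interferon, apoptosis and stromal lists. Monocyte and granulocyte genes rose in 7 of 11 cases (7 adjusted over the list alone). For this list, the group test gave camera adjusted p = 0.000881, or 0.0963 with an estimated correlation. They included CEBPD, a myeloid transcription factor (1.31 ± 0.15), and TYROBP, a receptor adaptor (1.61 ± 0.24). ITGAM, an integrin (1.31 ± 0.22), and CSF3R, a cytokine receptor (1.15 ± 0.19), rose too (all adjusted p = 5.28e-05 to 0.000911). Interferon genes rose in 6 of 11 (8 adjusted over the list alone), for example DDX58, a sensor of viral RNA, and IFIT3 (DDX58 (1.12 ± 0.14) and IFIT3 (1.28 ± 0.18)). The members together gave camera adjusted p = 0.000396, or 0.0963 with an estimated correlation. Genes of autophagy and lysosome rose in 7 of 22 (15 rose and 1 fell with the block, 9 adjusted over the list alone). Over all members the test gave camera adjusted p = 0.000396, or 0.0963 with an estimated correlation. Lysosomal proteins among them were NEU1 and LAMP2: NEU1 (0.99 ± 0.16) and LAMP2 (1.05 ± 0.20). Apoptosis regulators rose in 4 of 18 and fell in 1 (7 and 2 with the block, 6 and 1 adjusted over the list alone; camera adjusted p = 0.0550). The p53 targets rose in 4 of 15 and fell in 1 (6 and 4 with the block, 4 and 1 adjusted over the list alone; camera adjusted p = 0.261). BCL2L11 and PMAIP1, 2 promoters of cell death, rose and GADD45A fell: BCL2L11 (1.15 ± 0.16), PMAIP1 (1.49 ± 0.19) and GADD45A (-1.37 ± 0.20).

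In lists without a call on day 4, stem and progenitor genes fell in 3 of 10 (4 adjusted over the list alone; camera adjusted p = 0.0606). The 3 were LYL1, HHEX and MYB. HHEX lost its call without degron line 2 day 4 replicate 2 (0.0501), and among the 16 fits MYB stayed called only without parental day 0 replicate 2, degron line 1 day 0 replicate 1, parental day 4 replicate 1, LMO2 control day 4 replicate 1 or degron line 1 day 4 replicate 2. On day 4 itself LYL1 (-0.22, adjusted p = 0.0714) and HHEX (-0.27, 0.290) did not pass between degron and control lines. Of 23 integrated stress genes 3 fell and 1 rose (6 and 1 with the block, 3 and 1 adjusted over the list alone; 0.114), with SHMT2, a mitochondrial enzyme of serine metabolism, lower (-1.09 ± 0.15). Immediate early genes had ETV4 lower of 16 (-1.70 ± 0.33; 1 adjusted over the list alone; 0.452). The megakaryocyte list had GP6 lower of 9 (-1.10 ± 0.22; 2 lower and 1 higher with the block, 1 and 1 adjusted over the list alone; 0.208). In JAK-STAT feedback MYC and STAT5A fell and SOCS2 and CISH rose of 13 (STAT5A (-1.0 ± 0.13), SOCS2 (1.55 ± 0.32) and CISH (0.80 ± 0.20); 3 and 4 with the block, 2 and 2 adjusted over the list alone; 0.496). The median was 0.26 and the mean -0.00, with a test in the lower direction. Of 12 iron genes HFE rose (1.28 ± 0.14) and TFRC fell (3 and 3 with the block, 1 and 1 adjusted over the list alone; 0.928). Here the median was 0.04 and the mean 0.10, with a test in the lower direction. None of 13 mitochondrially encoded genes passed (4 rose with the block, 0 adjusted over the list alone; MT-CO1 0.35 ± 0.14 (adjusted p = 0.0811); 0.832). Their median was -0.04 and the mean 0.12, with a test in the higher direction. Among lists too short to test, COL3A1 of the stromal list rose from near the floor (1.09 ± 0.21). CD3D of the lymphoid list fell from its day 0 level (-1.88 ± 0.45 (adjusted p = 0.00862)). On day 4 itself CD3D stood 0.85 higher in the degron lines than in the control lines (adjusted p = 0.0342).

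The day 4 and day 1 changes were then compared with each other, a test chosen after seeing the data that uses no day 0 library. KLF1 (-1.21), MYC (-0.83), CDC42EP1 (-1.39) and HBZ (-2.68) lay lower on day 4 than on day 1, and ALAS1 (1.68), SYT10 (1.86) and CTSC (1.39) higher. In all, 1092 genes differed (591 higher, 501 lower), or 2616 with the block (1362 and 1254). Leaving out 1 library gave 653 (without degron line 2 day 4 replicate 2) to 974, with 727 without degron line 2 day 1 replicate 1. Cell division and cholesterol genes were lower on day 4. This held for 19 of 24 G2 and M phase genes (19 adjusted over the list alone). The group test here gave camera adjusted p = 1.51e-21, or 0.0157 with an estimated correlation, 0.0836 with the block as well. It also held for 11 of 24 cholesterol genes (15 adjusted over the list alone; adjusted p = 0.0157 with an estimated correlation, 0.0836 with the block as well). S phase genes were lower in 11 of 25 cases (19 with the block, 15 adjusted over the list alone). The list gave camera adjusted p = 1.59e-13, or 0.144 with an estimated correlation. Autophagy and lysosome genes were higher in 5 of 22 (12 with the block, 7 adjusted over the list alone). Camera gave adjusted p = 3.33e-05, or 0.0853 with an estimated correlation. All 12 genes called on day 1 were also called on day 4 in the same direction, where independent lists would share 2.38. Lists of the same sizes, taken by p-value from unchanged groups simulated against the same day 0 libraries, shared 8.85 (highest 11). The correlation of the 2 changes across genes, which are not independent replicates, was 0.684 (simulated 0.5) and their covariance 0.101 (simulated 0.0419, difference 0.0586). The shared day 0 libraries may give part of the excess. On the days themselves, without day 0, r was 0.851, but line differences present on day 0 enter both.

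The lines were also compared on day 0, before dTAGv1. KIT, a receptor of blood progenitors, ALDH1A1, a retinal-oxidizing enzyme, and S100A4, a calcium-binding protein, stood higher in the degron lines than in the control lines, and CHST2, a sulfotransferase, FAM89A and GAL, a neuropeptide, lower (genes chosen after their values were seen). The values were KIT (2.80 ± 0.16), ALDH1A1 (3.04 ± 0.23), S100A4 (2.42 ± 0.24), CHST2 (-2.02 ± 0.16), FAM89A (-2.39 ± 0.17) and GAL (-1.99 ± 0.23), adjusted p = 6.80e-08 to 3.12e-05. LMO2 stood at 0.60 ± 0.24 (adjusted p = 0.106), called with the block (adjusted p = 0.0309). This averages over unlike control lines, since LMO2 in the degron lines lay above parental cells and below the LMO2 control line. GATA1 was lower (-0.28 ± 0.09 (adjusted p = 0.0393)), and LDB1 (-0.25 ± 0.12 (adjusted p = 0.178)) and KLF1 (-0.29 ± 0.14 (adjusted p = 0.2)) did not pass. In all, 2576 genes differed (1633 higher, 943 lower), or 4729 with the block (2751 and 1978), all with 1 sign in both bio reps. These p-values rest on spread within lines, not between them. Lines as replicates gave 895 genes, and the 2 control lines differed in 280. After trimmed-mean rescaling 1432 were higher and 1170 lower. Genes of autophagy and lysosome were higher in 12 of 22 cases (14 adjusted over the list alone). Camera gave adjusted p = 6.18e-06, or 0.116 with an estimated correlation. Monocyte and granulocyte genes were so in 5 of 11 (5 adjusted over the list alone). The list gave camera adjusted p = 0.00162, or 0.167 with an estimated correlation. Immediate early genes were higher in 5 of 16 (6 adjusted over the list alone). Here camera gave adjusted p = 0.0167, or 0.340 with an estimated correlation. MYC and ribosome biogenesis genes were lower in 4 of 24 (21 with the block, 4 adjusted over the list alone). The members gave camera adjusted p = 6.18e-06, or 0.461 with an estimated correlation. S phase genes were lower in 6 of 25 (10 with the block, 6 adjusted over the list alone). These genes gave camera adjusted p = 0.00411, or 0.576 with an estimated correlation. Globins were lower in 1 of 10 (6 with the block, 1 adjusted over the list alone). The group test here gave camera adjusted p = 0.0101, or 0.516 with an estimated correlation. HIF targets had 5 of 19 higher, also adjusted over the list alone, with camera adjusted p = 0.0510, or 0.0142 with the block. Ribosomal protein genes were lower in 1 of 27 (11 with the block, 1 adjusted over the list alone) and cholesterol genes in 4 of 24 with 1 higher (7 and 2 with the block, 4 and 1 adjusted over the list alone). Apoptosis regulators were higher in 4 of 18 (8 with the block, 5 adjusted over the list alone). These lists and those of stem and progenitor, G2 and M phase and interferon genes were called too (camera adjusted p = 0.000620, 0.0174, 0.0466, 0.0240, 0.0201 and 0.0205). None of the 12 called lists held with an estimated correlation (adjusted p = 0.116 or more).

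To measure what dTAGv1 and time did without a degron, the control lines were compared with their own day 0. Cholesterol synthesis genes lay higher on day 1, with a median of 0.35 over 24 genes, 0 passing over all genes and 10 adjusted over the list alone. Taking all members at once gave camera adjusted p = 9.85e-24, or 0.00325 with an estimated correlation. Immediate early genes lay higher as well (median 0.33 over 16 genes, 0 passing and 1 adjusted over the list alone). As a group these genes gave camera adjusted p = 1.07e-08, or 0.0287 with an estimated correlation, 0.0826 with the block as well. Autophagy and lysosome genes (0 of 22; camera adjusted p = 7.44e-05, or 0.0878 with an estimated correlation) and HIF targets (0 of 19; camera adjusted p = 0.0439, or 0.919 with an estimated correlation) lay higher too. On day 4 the cholesterol list was still higher (0 of 24 passing, 3 adjusted over the list alone). The list as a whole gave camera adjusted p = 3.58e-10, or 0.0968 with an estimated correlation. Ribosomal proteins (camera adjusted p = 3.58e-10, or 0.618 with an estimated correlation) and mitochondrially encoded genes (camera adjusted p = 7.20e-06, or 0.351 with an estimated correlation) were lower. Lists of erythroid membrane (camera adjusted p = 0.0125, or 0.679 with an estimated correlation), globins (camera adjusted p = 0.0270, or 0.656 with an estimated correlation) and heme synthesis (camera adjusted p = 0.0495, or 0.679 with an estimated correlation) were lower as well, and each of these 5 lists had 0 members passing over all genes or adjusted over the list alone. The p53 targets, 0 of 15 passing, were called with the block only (camera adjusted p = 0.0803 and 0.0730 on days 1 and 4, 0.0471 and 0.0392 with the block). No single gene was called by limma on day 1 (657 at unadjusted p under 0.05) or day 4 (509), nor with the block. Without parental day 1 replicate 2 or LMO2 control day 1 replicate 2, 2 genes were called on day 1.

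The 2 degron lines were compared in their response. PDE11A, a phosphodiesterase of cyclic nucleotides, rose by 2.59 in line 1 and changed by 0.12 in line 2 on day 4 (difference 2.47 ± 0.21, adjusted p = 7.66e-05). SLITRK6, a neuronal membrane protein, changed by 0.53 and 1.83 (difference -1.30 ± 0.18, adjusted p = 0.0250) at a mean of 0.363 FPKM. These genes, named after their values were seen, were the only 2 called (471 at unadjusted p under 0.05; 4 with the block, 3 higher and 1 lower). Only 1 was called without any 1 of degron line 1 day 0 replicate 1 or 2, degron line 2 day 0 replicate 1 or 2, degron line 1 day 4 replicate 1 or 2, or degron line 2 day 4 replicate 2. On day 1 limma called 0 (130 at unadjusted p under 0.05, 218 with the block). A set of 3 lists differed on day 4 with an estimated correlation. G2 and M phase and cholesterol genes stood higher in line 1 than in line 2 (medians 0.57 and 0.38) and autophagy and lysosome genes lower (-0.22), each with adjusted p = 0.0433 with an estimated correlation, or 0.164 with the block as well. With the preset correlation camera also called stem and progenitor (0.000845), S phase (0.000217), histones (0.0147), ribosomal proteins (0.0249) and erythroid transcription factors (0.0341), all higher in line 1. None of these held with an estimated correlation (adjusted p = 0.162 or more).

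In HEL, TAL1 RNA was examined first. It fell from 466 ± 26.2 CPM with the non-targeting pool to 179 ± 12.8 with pool 1 and 188 ± 7.83 with pool 2 (n = 3 each; both pools -1.34 ± 0.07 (adjusted p = 6.31e-07)). In counts, TAL1 stood at 11679, 10995 and 11448 in the non-targeting libraries, 3695, 4277 and 3847 with pool 1 and 4500, 3722 and 3181 with pool 2. LMO2 (0.00 ± 0.07 (adjusted p = 0.986)) and LDB1 (0.07 ± 0.09 (adjusted p = 0.784)) did not pass.

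The effect of TAL1 knockdown was taken over both pools. Among the largest falls were HBA2 (-1.80 ± 0.29 (adjusted p = 0.00806)) and HBA1 (-1.37 ± 0.16 (adjusted p = 0.000994)), the alpha globins, and HBE1, the epsilon globin (-1.39 ± 0.09 (adjusted p = 6.80e-06)). ADD2, a membrane skeleton protein (-1.33 ± 0.17 (adjusted p = 0.00156)), and ALAS2, the erythroid enzyme that opens heme synthesis (-1.15 ± 0.17 (adjusted p = 0.00373)), fell as well. CCR4, a chemokine receptor, fell too (-1.12 ± 0.20 (adjusted p = 0.00954), or 0.0571 without non-targeting replicate 3). RPS9, a ribosomal protein, fell (-1.82 ± 0.22 (adjusted p = 0.00313)), but its non-targeting libraries spread widely (211 ± 81.7 CPM, against 57.1 ± 4.08 and 62.7 ± 8.45). EPAS1, a hypoxia-inducible factor, PHLDA1, an early response gene, GBP5, a guanylate-binding protein, CD48, a surface protein of leukocytes, SLA, an adaptor of receptor signalling, and AHNAK, a scaffold protein, rose. Their changes were EPAS1 (1.71 ± 0.16), PHLDA1 (1.55 ± 0.18), GBP5 (1.48 ± 0.22), CD48 (1.31 ± 0.18), SLA (1.26 ± 0.11) and AHNAK (1.17 ± 0.17), adjusted p = 7.31e-05 to 0.00410. CST7, a cystatin, rose by 2.07 ± 0.35 (adjusted p = 0.0119) and lost its call without 1 of 2 libraries (adjusted p = 0.0512 without non-targeting replicate 1 and 0.0758 without non-targeting replicate 3). NEDD9, a docking protein, rose by 1.29 ± 0.27 (adjusted p = 0.0306). NEDD9 lost its call without non-targeting replicate 1 or 3, or replicate 2 or 3 of either pool (0.0643 to 0.159). Of 16688 genes 338 were called (201 higher, 137 lower), 33 and 16 of them at least 2-fold. All 338 had 1 sign within each replicate number and 334 in both pools.

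The 3 libraries numbered 1, 1 in each group, stood apart from the other 6. Within groups, chi-square per degree of freedom was 20.4 to 30.6 against them and 4.39 to 5.87 between replicates 2 and 3. Without them 2139 genes were called (1082 higher, 1057 lower), a setting chosen after seeing the data. A block on the number gave 2437. The main fit and fits without 1 library lack it, so a lost call in HEL may reflect the spread by number. Leaving out non-targeting replicate 1, 2 or 3 gave 221, 133 or 104. Leaving out pool 1 replicate 2 or 3 gave 176 or 184, and pool 2 replicate 1, 2 or 3 gave 570, 161 or 216.

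In HEL 7 lists were lower by camera, 2 of them also with an estimated correlation. Globins fell in 5 of 9 cases (7 adjusted over the list alone; camera adjusted p = 8.26e-24, or 0.00643 with an estimated correlation). HBG2, a fetal globin, fell (-1.0 ± 0.09 (adjusted p = 7.31e-05)). Erythroid membrane genes fell in 11 of 24 (15 adjusted over the list alone). Tested as a group, the list gave camera adjusted p = 1.53e-19, or 0.00896 with an estimated correlation. They included CA1, a carbonic anhydrase, BLVRB, a reductase of heme breakdown, and EPB42, a membrane skeleton protein: CA1 (-0.87 ± 0.06), BLVRB (-0.97 ± 0.13) and EPB42 (-0.53 ± 0.08). Heme synthesis genes fell in 4 of 14 (7 adjusted over the list alone), UROD by 0.51 ± 0.07. For this list, the group test gave camera adjusted p = 1.61e-07, or 0.154 with an estimated correlation. Erythroid transcription factors fell in 3 of 15 (4 adjusted over the list alone), KLF1 (-0.53 ± 0.10 (adjusted p = 0.0182)) and TAL1, the siRNA target, among them. The members, TAL1 included, gave camera adjusted p = 0.000300, or 0.154 with an estimated correlation. The list was not tested without TAL1. KLF1 lost its call without non-targeting replicate 1, 2 or 3 (0.0585, 0.0754 and 0.0776). S phase genes fell in 3 of 25 (15 adjusted over the list alone). Over all members the test gave camera adjusted p = 1.82e-12, or 0.266 with an estimated correlation. MCM3, a helicase subunit, was among them (-0.35 ± 0.07), and its call was lost without 1 of 3 libraries (0.0668 without non-targeting replicate 2, 0.141 without non-targeting replicate 3 and 0.0568 without pool 1 replicate 2). None of 25 genes of MYC and ribosome biogenesis passed (2 lower adjusted over the list alone). The group test here gave camera adjusted p = 0.000229, or 0.668 with an estimated correlation. Of 14 genes of the LMO2 complex TAL1, the siRNA target, and CBFA2T3, a corepressor, fell (4 lower and 2 higher adjusted over the list alone). The median was 0.01 and the mean -0.09, with a test in the lower direction. Camera gave adjusted p = 0.0213, or 0.266 with an estimated correlation. The list was not tested without TAL1, so its call may rest on the target. CBFA2T3 (-0.32 ± 0.07 (adjusted p = 0.0462)) lost its call without non-targeting replicate 1, 2 or 3 (0.0684, 0.136 and 0.269). The same held without pool 1 replicate 2 or 3 (0.126 and 0.109) and pool 2 replicate 2 or 3 (0.123 and 0.0555).

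In HEL 3 lists were higher by camera, none of them with an estimated correlation. Mast cell and basophil genes rose in 3 of 11 cases (7 higher and 1 lower adjusted over the list alone). As a group these genes gave camera adjusted p = 6.12e-07, or 0.154 with an estimated correlation. HDC, which makes histamine, rose (0.45 ± 0.06 (adjusted p = 0.00183)). CPA3, a mast cell protease (1.11 ± 0.19; adjusted p = 0.0102, or 0.0517 without non-targeting replicate 3), rose, as did IL1RL1, a cytokine receptor (0.86 ± 0.15; adjusted p = 0.0117, or 0.0897 without non-targeting replicate 3). Stem and progenitor genes rose in 2 of 14 (7 higher and 1 lower adjusted over the list alone). The list as a whole gave camera adjusted p = 5.23e-05, or 0.154 with an estimated correlation. Both CD44, a hyaluronan receptor (0.73 ± 0.09), and MYCN, a relative of MYC (1.01 ± 0.17; adjusted p = 0.00813, or 0.0556 without non-targeting replicate 2), rose. ITGAM was the only one of 13 monocyte and granulocyte genes to rise (0.98 ± 0.15 (adjusted p = 0.00383); 2 adjusted over the list alone). Tested as a group, the list gave camera adjusted p = 0.00171, or 0.266 with an estimated correlation. No camera call was made for megakaryocyte (adjusted p = 0.413), lymphoid (0.127), G2 and M phase (0.337), cholesterol (0.0816), integrated stress (0.337), interferon (0.0956), p53 (0.386), apoptosis (0.246), immediate early (0.127), mitochondrially encoded (0.246), histone (0.614) or ribosomal protein (0.246) lists. In 4 further lists without a call median, mean and test differed in sign: HIF targets (median 0.01, mean 0.03, test lower, 0.943), iron handling (-0.02, 0.01, test higher, 0.671), JAK-STAT feedback (-0.01, 0.04, test higher, 0.652) and autophagy (0.03, -0.00, test higher, 0.337).

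**Figure D2:**
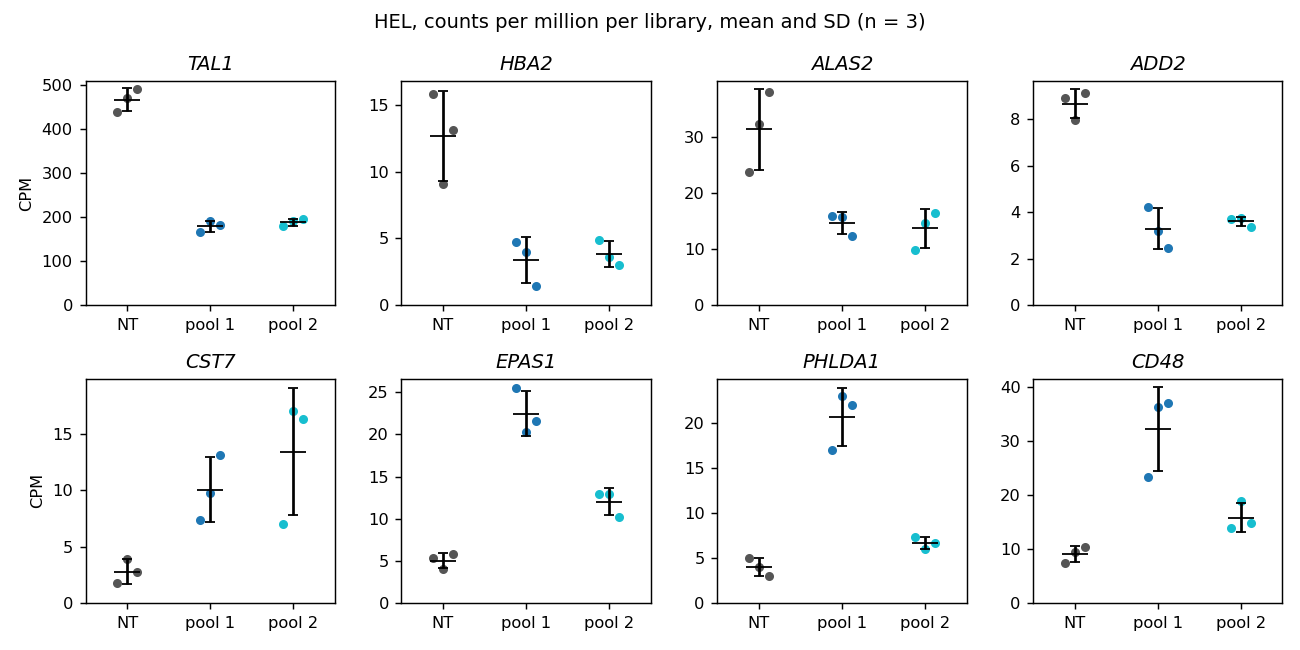
CPM of 8 genes in HEL cells with the non-targeting pool and TAL1 siRNA pools 1 and 2, with 1 point per library, the mean and SD of 3. TAL1, HBA2, ALAS2 and ADD2 lie lower with both pools, and CST7, EPAS1, PHLDA1 and CD48 higher, with PHLDA1 and CD48 higher with pool 1 than with pool 2.

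The 2 pools were compared with each other. TAL1 was lowered by a like amount (-1.38 with pool 1 and -1.31 with pool 2, difference -0.07 ± 0.08, adjusted p = 0.746). EPAS1, PHLDA1 and CD48 rose further with pool 1: EPAS1 (2.16 and 1.26, difference 0.90 ± 0.16, adjusted p = 0.0116), PHLDA1 (2.36 and 0.73, difference 1.63 ± 0.19, adjusted p = 0.00110) and CD48 (1.83 and 0.80, difference 1.03 ± 0.19, adjusted p = 0.0129). Other differences, in genes chosen after their values were seen, were of PLA2G4A (0.10 and -1.67, difference 1.76 ± 0.12, adjusted p = 1.78e-05), CAPZA1 (-1.61 and -0.06, difference -1.55 ± 0.12, adjusted p = 4.27e-05) and EVI2B (3.30 and 0.62, difference 2.68 ± 0.28, adjusted p = 0.000518). In all, 461 genes differed between pools (281 higher and 180 lower with pool 1), and leaving out libraries gave 144 without pool 1 replicate 2, 156 without pool 1 replicate 3, 128 without pool 2 replicate 2 and 137 without pool 2 replicate 3. Monocyte, mast cell and interferon lists stood higher and S phase lower with pool 1 (camera adjusted p = 0.00107, 0.00107, 0.0263 and 0.00107). Members higher with pool 1 were 3 of 13, 4 of 11 and 1 of 22 (3, 4 and 5 adjusted over the list alone, with 1 interferon gene lower), and 2 of 25 S phase genes were lower (2 adjusted over the list alone). None held when the correlation was estimated (adjusted p = 0.608, 0.608, 0.608 and 0.969 with an estimated correlation). Against the non-targeting pool, pool 1 changed 704 genes (428 higher, 276 lower). Its count was 347 or 286 without non-targeting replicate 2 or 3, and 285 or 279 without pool 1 replicate 2 or 3. Pool 2 changed 176 (82 higher, 94 lower), which became 110 without non-targeting replicate 1, 82 without non-targeting replicate 2, 46 without non-targeting replicate 3, 296 without pool 2 replicate 1, 35 without pool 2 replicate 2 and 56 without pool 2 replicate 3. Of these, 51 rose and 35 fell with both pools. Independent lists would share 2.10 and 1.55. Lists of the same sizes, taken by p-value from unchanged groups simulated against the same 3 controls, shared 32.2 and 20.8 (highest 41 and 30). Log2 changes correlated across genes, which are not independent replicates, at 0.506, within the simulated range (mean 0.486, highest 0.510). Their covariance was 0.0834 (simulated 0.0446, highest 0.0483, difference 0.0388). Part of the excess in shared calls may come from the shared controls.

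LDB1 knockdown in K562 was described from 3 libraries without a replicate check. LDB1 itself stood lower with both shRNAs (468 to 62.4 and 69.6 TPM, log2 ratios -2.89 and -2.73). LMO2 was lower as well (131 to 44.2 and 46.2 TPM, -1.55 and -1.48), and TAL1 went from 102 to 105 and 103 TPM. Among the furthest below the control were AHSP, a chaperone of alpha globin (35.3 to 2.97 and 2.72 TPM), and FAM178B (817 to 79.6 and 105 TPM). RLN3, a relaxin peptide (-3.45 and -2.80), and EPB42 (20.9 to 1.96 and 2.98 TPM) lay far below too. Among the furthest above were IGFBP5, a binding protein of insulin-like growth factors (0.179 to 80.0 and 49.7 TPM), CALB1, a calcium buffer (2.24 to 140.2 and 106 TPM), and ITGAX (0.537 to 42.7 and 33.7 TPM). PDE11A (0.489 to 48.4 and 30.9 TPM), NUPR1, a stress-induced nuclear protein (2.87 to 75.8 and 77.4 TPM), BMP6, a growth factor (4.37 and 4.21), and CDKN1A, an inhibitor of cell cycle kinases (7.16 to 139 and 141 TPM), lay far above too. By the 2-fold rule 1113 genes lay higher and 275 lower with both shRNAs, and 0 lay 2-fold apart in opposite directions. With ratios centred on their medians (0.18 and 0.13) the numbers were 886 and 424. The libraries share their control, which raises such counts: independent libraries would share 162 and 15.6, and the 2 sets of ratios correlated at 0.919 across genes.

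The lists were then placed among random lists in the LDB1 libraries, by mean log2 ratios over both shRNAs. Globins lay low, 6 of 10 listed at least 2-fold (median -1.38, percentile 0; for example HBZ, 3781 to 432 and 771 TPM, and HBG2, 2439 to 699 and 883 TPM). So did erythroid membrane genes (5 of 22; median -0.69, percentile 0) and heme synthesis (2 of 14; median -0.66, percentile 0; ABCB10, 95.0 to 23.4 and 31.1 TPM). Erythroid transcription factors also lay low (4 of 12, the target LDB1 included; median -0.51, percentile 0.0300; KLF1, 531 to 111 and 165, MYB, 113 to 22.9 and 32, and GFI1B, 54.8 to 14.3 and 19.6 TPM). MYC and ribosome biogenesis (1 of 24; median -0.56, percentile 0) and ribosomal proteins (0 of 27; median -0.47, percentile 0) did too. Immediate early genes lay high, 8 of 17 listed (PHLDA1, 2.65 and 2.14; median 1.56, percentile 100). JAK-STAT feedback followed (6 of 13 higher and 1 lower; ID1, 55.4 to 531 and 334 TPM; median 1.07, percentile 100). Also high were monocyte and granulocyte genes (5 of 12 higher and 1 lower; ITGAM, 12 to 38.7 and 36.8 TPM; median 1.05, percentile 100) and HIF targets (4 of 20; EGLN3, 5.81 to 46.5 and 44.1 TPM; median 0.85, percentile 100). The same held for autophagy and lysosome (5 of 21; GABARAPL1, 18.8 to 103 and 101 TPM; median 0.81, percentile 100) and apoptosis regulators (5 of 18; PMAIP1 (1.76 and 1.61) and BMF (2.27 and 2.42); median 0.66, percentile 99.8). The p53 targets (4 of 16; median 0.45, percentile 96.3) and interferon genes (2 of 10; median 0.64, percentile 96.3) lay within the range of random lists. So did integrated stress (2 of 23; median 0.27, percentile 94.5) and cholesterol genes (2 of 24; median 0.25, percentile 91.8). With shRNA 2 alone p53, stress and cholesterol lists lay above it (97.8, 99.7 and 99.7). The megakaryocyte list (1 higher and 1 lower of 9) lay within it by mean ratios (median 0.66, percentile 95.1) and above it with each shRNA alone (99 and 97.9). Histones (0 of 10; percentile 78.7), stem and progenitor (2 higher and 2 lower of 9; 68.0), and LMO2 complex (1 higher and 2 lower of 14, LDB1 and LMO2; 51.0) lay within it too. The same held for mitochondrially encoded (0 of 13; 45.0), G2 and M phase (0 of 23; 27.3), iron handling (1 lower of 12; TFR2, 222 to 67.3 and 93.4 TPM; 19.3) and S phase (0 of 24; 6.58). In lists too short to place, CD3D (27.5 to 174 and 185 TPM) and SPARC (1.52 to 42.4 and 26.7 TPM) lay higher and KIT (-2.02 and -1.57) lower.

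**Figure D3:**
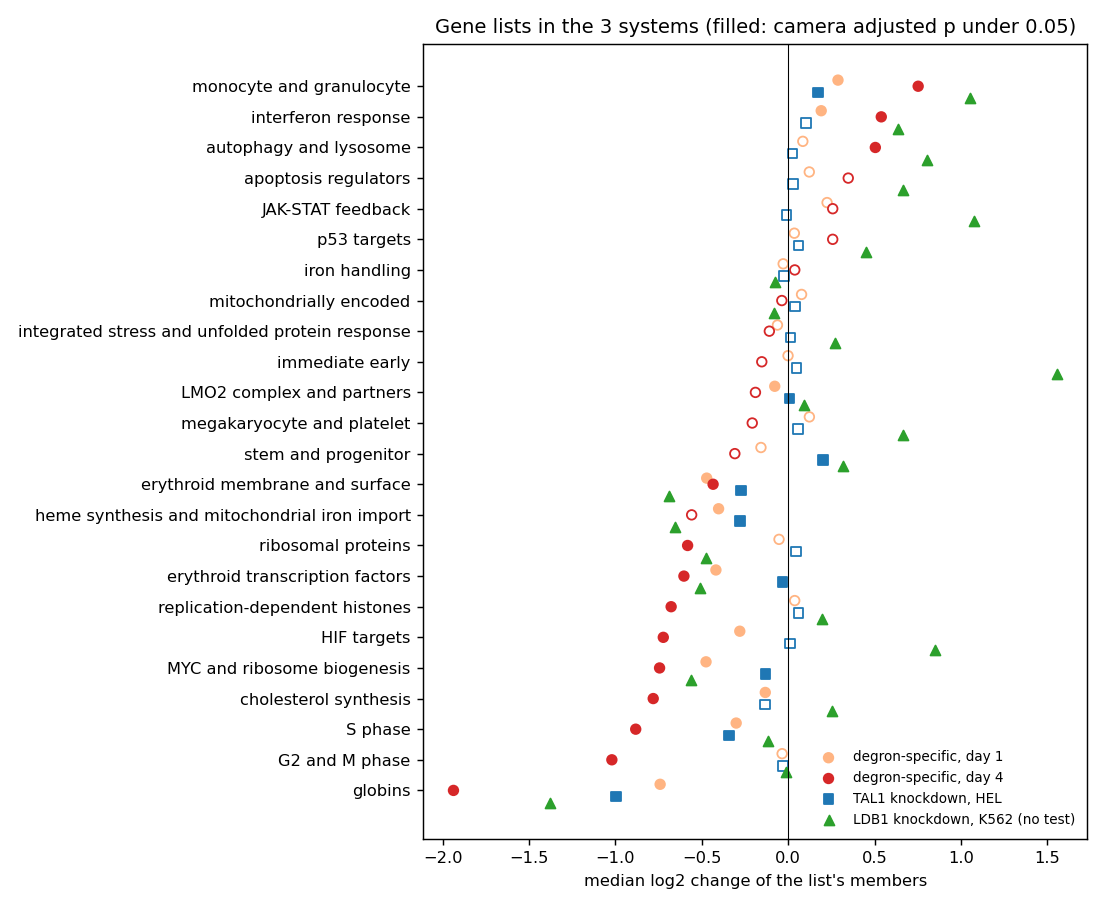
Median log2 change of 24 gene lists in the degron-specific day 1 and day 4 contrasts, TAL1 knockdown in HEL and LDB1 knockdown, with filled points where camera with a preset correlation gave an adjusted p under 0.05; the LDB1 libraries have no test. Globin and erythroid membrane lists lie below 0 and the monocyte list above 0 in all 4.

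Finally, genes called after TAL1 knockdown in HEL were followed in the K562 sets, which share no library with HEL. Of 119 genes higher in HEL and measured in the degron set, 44 rose and 8 fell on day 4 (49 and 9 adjusted over the list alone; mean 0.40, adjusted p = 0.0356 with an estimated correlation). On day 1, 1 rose (13 higher and 1 lower adjusted over the list alone; mean 0.25, 0.00926 with an estimated correlation). Of 108 genes lower in HEL, 39 fell and 7 rose on day 4 (48 and 8 adjusted over the list alone; mean -0.66, adjusted p = 0.00624 with an estimated correlation). On day 1, 2 fell (11 lower and 1 higher adjusted over the list alone; mean -0.36, 0.00624 with an estimated correlation). Among 10361 genes tested in both tables, the overlaps of 44 and 39 compare with 15.2 and 10.1 for independent lists (Fisher's exact test, two-sided, odds ratios 4.11 and 5.67, adjusted p = 2.66e-11 and 9.31e-14 over 4 tests). Opposite overlaps were 7 against 13.8 (adjusted p = 0.0770) and 8 against 11.1 (0.427). In the LDB1 libraries, 47 of 124 listed HEL-higher genes lay 2-fold higher and 0 lower (percentile 100 among random lists), and of 106 HEL-lower genes 20 lay 2-fold lower and 2 higher (percentile 0). ITGAM rose in both tested systems (in HEL by 1.57 with pool 1 and 0.38 with pool 2, difference adjusted p = 0.00273) and lay 1.61 and 1.54 higher in the LDB1 libraries, and KLF1 fell in both and lay at -2.25 and -1.68. Genes share regulation and are not independent, so Fisher's test gives p-values that are too small.

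**Figure D4:**
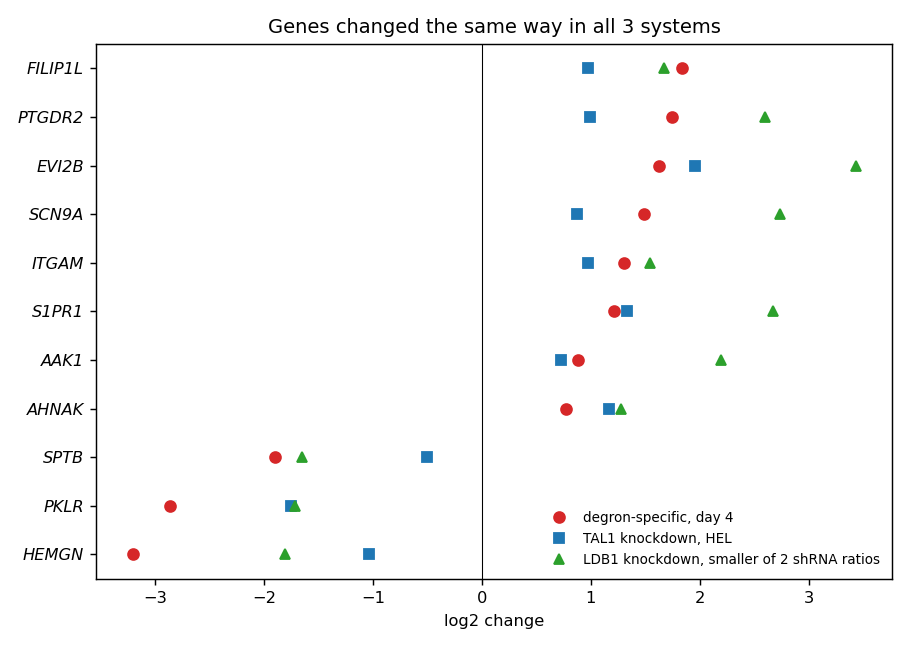
Log2 change of 11 of the 34 genes called in 1 direction in the degron-specific day 4 contrast and in HEL and at least 2-fold in both LDB1 shRNA libraries (the smaller ratio is drawn). The genes drawn kept both calls with each library left out, and 8 lie above 0 and 3 below in all 3 systems.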

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

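The comparison of day 4 with day 1, with its gene values, was chosen after the data were seen; the tests between pools and between degron lines were not. Between degron lines, 2 genes, PDE11A and SLITRK6, differed in their day 4 response by limma. The degron-specific change differed between day 4 and day 1 for 1092 genes. Day 4 minus day 1 was lower by that test for KLF1 (-1.21), MYC (-0.83), CDC42EP1 (-1.39), UROD (-0.48), DHRS11 (-0.73), TTLL12 (-0.57), AP001531.1 (-2.265) and HBZ (-2.68) on the log2 scale. It was higher for CYTH1 (0.76), ALAS1 (1.68), SYT10 (1.86), SOSTDC1 (1.68), P2RX6 (1.13), CTSC (1.39) and SCPEP1 (1.15).

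The TAL1 siRNA pools differed in 461 genes by edgeR, among them EPAS1 (0.90), PHLDA1 (1.63) and CD48 (1.03 log2 higher with pool 1). A stronger knockdown by pool 1 would give changes of 1 sign, larger with pool 1. Only 26.68% of the 461 genes had that form. Opposite signs (67.7%) were of any size, with 0 genes called in opposite directions. TAL1 differed by -0.07 ± 0.08 (adjusted p = 0.746), which argues against stronger knockdown as the whole cause. Thinning argues against lower depth of some pool 2 libraries: at the shallowest total (15.9 M) for all, 465 genes differed. Effects on other transcripts may account for the difference and stay open, as siRNA sequences were not used here. No biological explanation was tested.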

How the results depend on the processing

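The fits with HEL replicates 2 and 3 only, the thinned counts and all settings of the day 4 against day 1 comparison were chosen after seeing the data. Leaving out 1 library gave 1 to 12 called genes on day 1, 2362 to 3312 on day 4, 1742 to 2546 between lines on day 0, 0 to 2 and 0 to 0 in the control lines on days 1 and 4, 0 to 0 and 1 to 3 between degron lines on days 1 and 4, and 653 to 974 between days. In HEL it gave 104 to 570 for both pools, 279 to 722 for pool 1, 35 to 296 for pool 2 and 128 to 592 between pools. In the following, values stand in the order day 1, day 4, day 0 or as named. A replicate block gave 167, 5471 and 4729 genes, 4 between degron lines on day 4 and 2616 between days, and apart from the values printed with the block it changed no other call of a named gene or list. HEL replicate numbers missed the bound for pairing, an r over 0.1 in every pair (9 pairs, r 0.0869 to 0.363, median 0.123; 6 of 9 libraries correlated best with their own number), although those numbered 1 stood apart, and a block on the number gave 2437, 2888, 1694 and 2431 genes for both pools, pool 1, pool 2 and between pools. Replicates 2 and 3 only gave 2139, 2705, 1652 and 2591. Without a filter 40 genes were called on day 1, 23 in the control lines on each day, 10 and 59 between degron lines, and 716, 1084, 418 and 758 in HEL in the order above. At a mean FPKM of at least 5, with fewer genes tested, day 4 gave 1774, day 0 1419 and degron lines on day 4 0, and a pseudocount of 0.1 gave 1 there. With the parental line as the only control day 1 gave 0 and day 4 1763, with LMO2 control alone 1, 1675 and 1626, with degron line 1 alone 0, 1398 and 1197, and with line 2 alone day 1 gave 5, all with fewer libraries. Degron lines against their own day 0 gave 656 and 6044, against the control lines of that day 5359 and 8315, and lines as replicates 448, 6607 and 895, with 7 in the control lines on day 4. DESeq2 gave 687 for both pools, 382 for pool 2 and 776 between pools, and fitting only the compared groups gave 100 for pool 2. LDB1 counts became 737 at a highest TPM of at least 20, 3426 at 1.5-fold and 3471 with the shRNAs taken as replicates in limma. With an estimated correlation 1, 0, 0 and 2 lists were called on day 1, day 4, day 0 and in HEL, against 11, 13, 12 and 10, and fry called 1 on day 1. Where fewer genes or libraries do not account for a change, the cause was not tested.

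CD3D, lower on day 4 (-1.88), was higher (0.85) against the control lines of that day. LMO2 in HEL (0.00, not called) took values of -0.0543 without non-targeting replicate 1, -0.00855 without pool 1 replicate 2, -0.00870 without pool 2 replicate 2 and -0.00703 with replicates 2 and 3 only, and up to 0.0399 without non-targeting replicate 2. Named genes otherwise kept their direction. With 1 library left out, a named gene lost its call 105 times on day 1, 59 times on day 4 and 88 times in HEL. Under other settings this happened 41, 73 and 3 times, and a gene without a call gained one 5 times on day 1 and 3 times on day 4. LDB1 values moved by more than the spread between shRNAs 70 times with another pseudocount or centred ratios. At these depths and group sizes simulated 2-fold changes were recovered in 58% of cases on day 4 and 54% in HEL, so smaller changes can be missed, and the depth of the LDB1 libraries is unknown.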

Other observations

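Tests of genes moving in 3 systems, of LDB1 genes in the degron set, of lower complex activity, of differences between lines, of 1 scaling factor per library (both patterns) and of splits by HEL replicate number were chosen after the results were seen. Among 8911 genes measured in all 3 systems, 25 rose and 9 fell in the degron-specific day 4 contrast and in HEL and lay at least 2-fold in the same direction with both LDB1 shRNAs, against 1.01 and 0.146 for independent systems. Only 12 of the 34 kept both calls with each library left out, 9 higher and 3 lower. Of these, genes called with each TAL1 pool, with log2 changes on day 4, in HEL and the smaller LDB1 ratio, were HEMGN (-3.21, -1.04 and -1.81), PKLR (-2.86, -1.75 and -1.72) and SPTB (-1.90, -0.50 and -1.65) among the lower. Higher ones were AHNAK (0.78, 1.17 and 1.28), AAK1 (0.88, 0.73 and 2.20), SCN9A (1.49, 0.87 and 2.74) and PTGDR2 (1.74, 0.99 and 2.60). HEMGN and SCN9A changed more with pool 1 (adjusted p = 0.00372 and 0.00790 between pools). AAK1 is a kinase of endocytosis, SCN9A a sodium channel and PTGDR2 a prostaglandin receptor. Others, called in HEL with pool 1 and not with pool 2, included ITGAM (1.57 and 0.38), EVI2B (3.30 and 0.62), S1PR1 (2.14 and 0.52) and FILIP1L (1.44 and 0.52), with log2 changes for pools 1 and 2 and adjusted p = 0.000518 to 0.00399 between pools. EVI2B is a surface protein of leukocytes, S1PR1 a receptor of lymphocyte egress and FILIP1L a protein linked to the cytoskeleton.

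Genes that lay 2-fold apart in the LDB1 libraries also moved in the degron set. Of 866 genes higher there, 307 rose and 39 fell on day 4 (camera p = 0.00895 with an estimated correlation), and of 227 lower, 53 fell and 3 rose (p = 0.0181 with an estimated correlation). Both sets come from K562, but no library is shared. Of the 200 genes with the largest day 4 rises, 116 lay 2-fold higher and 2 lower in the LDB1 libraries (percentile 100 among random lists), and of the 200 with the largest falls, 24 lay lower and 12 higher (percentile 0).

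Degron lines on day 0 already differed from the control lines in the direction of the later change: 999 genes were called on day 0 and on day 4, 857 of them in 1 direction (600 higher, 257 lower). The shared day 0 libraries push the 2 contrasts apart in direction (r 0.233 across genes, simulated -0.705). A scaling factor common to all genes of a library is argued against as the whole cause, since it moves genes 1 way and 29.99% of the 857 were the lower ones, while trimmed-mean rescaling (84.42% in 1 direction) moved the median of all genes by only -0.04 and tests nothing further. Lower activity of the LMO2 complex before dTAGv1 may account for part of the pattern: genes higher and lower after TAL1 knockdown in HEL stood higher and lower on day 0 (larger of the 2 camera p = 0.01504 with an estimated correlation). Differences that arise between any K562 lines kept apart cannot be told apart from it, because only 1 pair of lines without a degron exists. LMO2 control minus parental on day 0 correlated with the day 4 change at 0.04134 across genes, with 280 genes called between those lines.

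S phase, G2 and M phase and ribosomal protein lists fell by day 4, with medians of -0.88, -1.02 and -0.58, against -0.30, -0.03 and -0.05 on day 1. A scaling factor common to all genes of a library is argued against, since the highest of the 3 medians lay at -0.6451 from the median of all genes, while trimmed-mean rescaling (-0.6311) moved that median by only -0.04 and tests nothing further. The bio rep batch is argued against by a highest median of -0.5303 within bio rep 1 or 2. Mitochondrial genes, 17.7% to 27.2% of FPKM per library, are argued against as well, since without them the highest median was -0.4989. Growth was not measured here, and no biological explanation was tested.

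The groups were also split in every other way. Of 35 splits of the 8 line-by-replicate series, 1 split, the real one, gave as many genes on day 1 (565, highest other 131) and on day 4 (6381, highest other 44). Of 35 splits of the 8 day 0 libraries 1 did (1104, highest other 103). Libraries of a line are not independent, however, and only 3 splits of whole lines exist (highest other 0 in each case), too few for a share under 0.05. Among the 35 the highest other split was each time that by bio rep, and among the 18 splits balanced for it the highest other values were 1, 0 and 0. For control lines between days all 35 of 35 splits gave at least the real value of 0, on day 1 and on day 4. The split by bio rep gave 3422 and 4034, which points to a structure of the samples by bio rep. In HEL, 3 of 84 splits into 6 and 3 gave at least the real 118 genes. The others were the 3 libraries numbered 1 against the rest (1939), a structure by replicate number, and pool 1 against the rest (482), a treatment grouping. Of 27 splits with 1 library of each number 2 reached 118, the real one and pool 1 against the rest. The 24 of these 27 that mixed the groups gave at most 1 gene, also with the number as a block (real 464, pool 1 against the rest 1272). This argues against a chance split of these libraries as the source of the 118 genes. With the pools as separate groups the block gave 2437. Of 10 splits for each pair of HEL groups 1 reached the real value: 553 for pool 1 (highest other 0), 100 for pool 2 (highest other 0) and 332 between pools (highest other 1), and 10 splits are too few for a share under 0.05.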
